A study of Mus musculus with 12 samples.

How the data were processed

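Total RNA of 12 tumours was sequenced on the BGISEQ-500 platform. 4T1 cells, a mammary carcinoma line derived from a BALB/c mouse, had been injected subcutaneously into the right flank of BALB/c mice, and the tumour-bearing mice were randomised to 4 arms of 5 mice. One arm was left as control, one received DSF by mouth, one received an antibody that blocks the immune checkpoint receptor PD-1 by intraperitoneal injection, and one received both. Each arm is represented by 3 libraries, each taken as the tumour of a different mouse, and the group and replicate of every library were taken from its title. The columns of the deposited table were matched to the titles by the groups of the deposited group plan, where columns named p are anti-PD-1, and by number. The name of 1 control column ends in 11, which was read as control 1 because columns for control 2 and 3 are there, and the numbers in the table are assumed to be those of the titles.

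Per the labels, the authors' processing named HISAT2 2.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5, without saying which step each tool performed. The deposited gene table holds expected counts, which are read counts per gene estimated by the authors, of which 9.02% are not whole numbers, and FPKM values for the same 12 libraries. The genome build was not stated, so genes are given by symbol and NCBI gene identifier and not by position. The deposited transcript table and the authors' own correlation and principal component tables were not used here. Mitochondrially encoded transcripts are not in the gene table, so that measure of RNA quality was not available.

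Expected counts were rounded, genes with too few counts were removed with filterByExpr given the 4 groups, and 14144 of 18433 genes were kept. Counts were scaled by TMM and fitted with the edgeR 4.0.16 quasi-likelihood model in R 4.3.3, with 1 mean per group and all 12 libraries in a single fit. The fitted comparisons were any difference among the 4 groups, DSF against control, anti-PD-1 against control, the combination against control, against DSF and against anti-PD-1, the interaction of both treatments, and the main effect of each treatment. The interaction is the log2 change with DSF in the presence of anti-PD-1 minus the change in its absence. A main effect is the mean of both groups given a treatment minus the mean of both groups not given it. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 were called. Levels are CPM on TMM-scaled library sizes, given as mean ± SD over 3 libraries per group, and log2 fold changes are given with the standard error derived from the quasi-likelihood statistic.

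Total counts per library ranged from 13323171 to 16809705. The share of counts taken by a list of marker genes in a single library is given with a 95% Wilson interval, which covers counting error only. On counts simulated without real differences, to which known changes had been added, the edgeR fit recovered 26.5% of genes changed 1.5-fold, 76% of genes changed 2-fold and 98% of genes changed 4-fold in the comparison of the combination with DSF. The changed genes had a mean of at least 5 CPM. A single set was drawn gene by gene from the dispersions of the edgeR fit, without outlying libraries, so these rates need not hold for the tumours. In the same simulation 3.64% of its calls were false. DESeq2 1.42.0 gave 17.8% false calls there, limma on log2 values 4.88%, and edgeR restricted to both groups compared 8.55%. For this reason DESeq2 counts are given beside the edgeR counts and not in their place, although a simulation drawn from edgeR dispersions may favour edgeR.

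Before the data were examined, 39 gene lists, the named-gene rule, the tests and the alternatives listed in the last paragraph were fixed, except where a later choice is stated. The lists cover interferon responses, antigen presentation, immune cell types, stroma, tumour epithelium, proliferation, metabolism, stress responses, pathways linked to DSF, and tissues that can surround a flank tumour. Of the 39 lists, 37 had at least 3 tested members and were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. The same lists were tested with camera using a correlation estimated from the data, and with fry, which asks whether the genes of a list move, on balance, in one direction without comparing them with other genes. In simulated counts without change, preset camera called 0 of 37 lists. Simulated genes vary independently, while genes of a list in a tumour vary together, so the test with an estimated correlation was run as well. For each list the members passing over all genes and those passing when adjusted over the list alone were counted. A list score is the mean over members of log2 CPM centred on each gene's mean across libraries. Scores were compared for both main effects by an exact permutation test within the arms of the other treatment, added after the data were seen, for which 400 arrangements make 0.005 the smallest possible p. Among 3 against 3 libraries an exact permutation test cannot go below 0.1 and was not used.

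Genes named in the text were the 8 with the largest rise and the 8 with the largest fall among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. Further named genes were the 4 members with the smallest p in each list called by preset camera, the 10 genes with the smallest p where no gene passed, and 16 genes chosen for their relation to PD-1, DSF and interferon. Predicted genes and Riken clones were counted but not named. Of the genes this rule gives, 2 are not reported here. Calls shared by the comparisons with control, and the correlation of their fold changes, were set against 100 simulated sets with unchanged groups and the same controls.

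The alternatives fixed at the outset were DESeq2, scaling by the RLE method, no filter, a filter of at least 5 CPM in 3 libraries, a fit of only the groups compared, the replicate number as a block, limma on log2(FPKM + 1), and leaving out each library in turn. Alternatives added after the data were seen were limma-voom with library weights, the skin and adipocyte scores as covariates, leaving out DSF replicate 2 where it enters only through the spread, and removing genes that followed the skin score within groups with a correlation above 0.8. The skin score itself differed between groups, with means of -1.98 in DSF and 2.17 in the combination (SD 1.11 and 0.978, n = 3 each). A fit with the covariates can therefore remove a treatment difference together with skin, and it cannot tell them apart. Lists were tested by preset camera alone in that fit. Splits of the 6 libraries of each pair of groups, 10 per pair, and 100 regroupings of the 12 libraries were refitted.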

Results

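Gene expression was measured in 12 flank tumours grown from 4T1 mouse mammary carcinoma cells in BALB/c mice. The tumours came from 4 randomised arms with 3 libraries each: control, DSF, anti-PD-1, and DSF with anti-PD-1 (the combination). DSF is the usual abbreviation of disulfiram, an aldehyde dehydrogenase inhibitor that also binds copper and inhibits inflammasome and p97-related pathways. Anti-PD-1 antibodies release T cells from inhibition by PD-L1, which is encoded by Cd274. Total counts per library lay between 13323171 and 16809705, and between 15902 and 16766 genes were detected in each. The FPKM values of 11 libraries correlated with one another across genes with Pearson's r of 0.971 to 0.995, while DSF replicate 2 correlated with the others at 0.91 to 0.922. Genes are not independent replicates, so these correlations describe similarity only. The coefficient of biological variation in the fit was 0.277.

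Some libraries had high shares of marker transcripts of tissues that can surround a flank tumour. Adipocyte markers such as Adipoq and Plin1 took 1.2% of the counts in DSF replicate 2 (95% Wilson interval 1.2 to 1.21%) and 0.00773 to 0.0752% in the other 11 libraries. Skin and hair follicle markers took 0.702% of the counts in combination replicate 2 (0.698 to 0.707%), 0.214% in combination replicate 3 (0.212 to 0.216%) and 0.0825% in combination replicate 1 (0.0812 to 0.0839%). The highest share among the other libraries was 0.0896% in anti-PD-1 replicate 1 (0.0882 to 0.091%). The DSF group had the lowest mean, at 0.0138% ± 0.0065 (SD, n = 3) against 0.0329% ± 0.0121 (SD, n = 3) in controls. Its libraries (0.00714 to 0.0201%) overlapped with those of control (from 0.0189%) and anti-PD-1 (from 0.0133%). Skeletal muscle markers took 0.0172 to 0.121% of the counts, and both of these extremes were combination libraries.

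**Figure D1:**
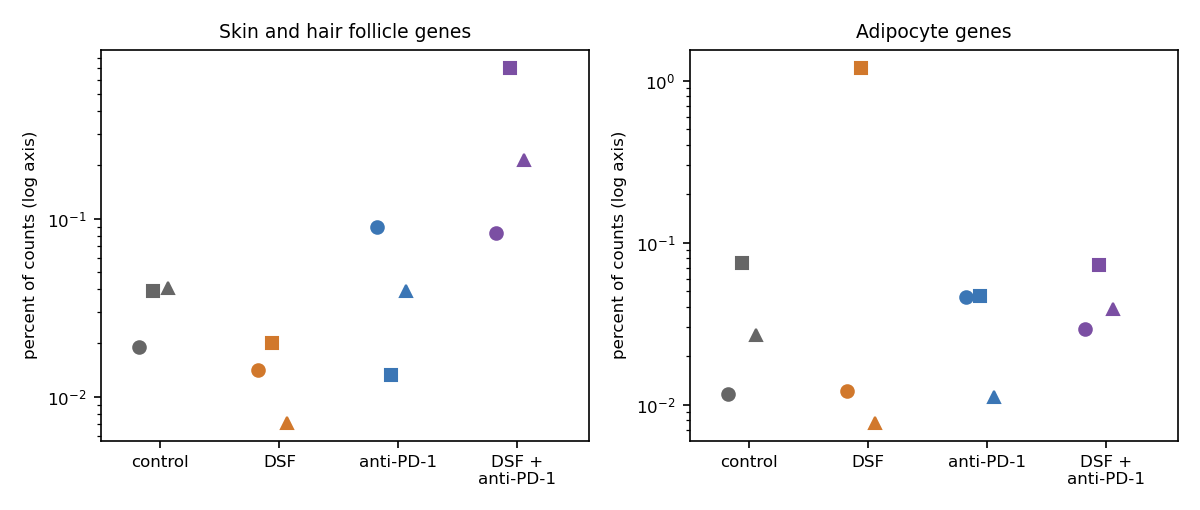
Share of each library's counts taken by skin and hair follicle markers and by adipocyte markers, in percent on a log axis, for the 4 groups (circle, square and triangle are replicates 1, 2 and 3). Adipocyte markers reached 1.2% in DSF replicate 2, and skin markers reached 0.702% in combination replicate 2.

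The first question was whether any gene differed among the 4 arms. The edgeR test over all groups called 0 of 14144 genes, with a smallest adjusted p of 0.0736. At an unadjusted p under 0.05 there were 1863 genes, where 707 would be expected without differences. The likelihood ratio test of DESeq2 called 870 genes. Leaving out a single library gave 41 genes without combination replicate 1, 5 without DSF replicate 1, and 3, 1 and 2 without anti-PD-1 replicates 1, 2 and 3.

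DSF against control asks what the drug did on its own. Interferon-stimulated genes had lower values in the DSF tumours: all 30 tested members of the type I interferon response list had negative log2 fold changes, with a median of -0.68. Irf7 (gene identifier 54123), the transcription factor that amplifies interferon production, was at 54.6 ± 9.84 CPM in DSF and 109 ± 30.6 CPM in control tumours (SD, n = 3 each; log2 fold change -0.99 ± 0.20 SE, adjusted p = 0.187). Parp14, an ADP-ribosyltransferase induced by interferon, was at 137 ± 17.2 against 226 ± 7.98 CPM and Ifi44 at 43.1 ± 5.45 against 97.5 ± 20.3 CPM. No member passed over all genes, and 25 of the 30 fell when adjusted over the list alone. The list was lower at adjusted p = 2.14e-31 by preset camera and at 0.0209 by fry, with adjusted p = 0.164 with an estimated correlation.

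Genes of antigen presentation to CD4 T cells followed the same direction in this comparison. All 10 MHC class II genes were lower in DSF (median log2 fold change -1.17), among them H2-Aa at 270 ± 61.4 against 583 ± 61.8 CPM and the invariant chain gene Cd74 at 649 ± 155 against 1346 ± 131 CPM. Of these genes, 8 fell when adjusted over the list alone and 0 over all genes (fry adjusted p = 0.0476, adjusted p = 0.235 with an estimated correlation). The interferon gamma list, with guanylate-binding proteins and the T cell attracting chemokines Cxcl9 and Cxcl10, had a median of -1.08. There, 20 of 22 members fell when adjusted over the list alone and 0 over all genes (adjusted p = 0.235 with an estimated correlation). Ciita, the master regulator of MHC class II transcription, was at 20.9 ± 7.22 against 48.9 ± 8.28 CPM. Cd274 was at 66.2 ± 18.9 against 96.9 ± 24.7 CPM (adjusted p = 0.444), and Ifng, the gene of interferon gamma, at 1.11 ± 0.622 against 4.17 ± 1.95 CPM (adjusted p = 0.272).

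Immune cell markers had lower medians in DSF than in control tumours: -0.61 for T cells, -0.64 for cytotoxic and NK cells, -0.90 for B and plasma cells, -0.25 for dendritic cells and -0.72 for mast cells and eosinophils. MHC class I genes had a median of -0.39 and skin markers of -1.51. Higher medians were found for hypoxia and glycolysis genes (0.27, positive in 24 of 25), NRF2 targets (0.16), immediate early genes (0.18) and the 4 erythrocyte genes (2.05), and proteasome genes were at -0.10 with 29 of 30 negative. Each of the lists in these sentences was called by preset camera and had an adjusted p = 0.371 with an estimated correlation. Further preset calls were immune checkpoint genes (median -0.44, adjusted p = 0.252 with an estimated correlation), regulatory T cell genes (-0.56, 0.388), macrophage markers (-0.27, 0.549) and neutrophil markers (0.27, 0.552). The same holds for inflammatory cytokines (0.39, 0.527), epithelial-mesenchymal transition genes (0.15, 0.388), mitotic genes (-0.12, 0.471) and pyroptosis genes (-0.39, 0.235), where the number after the median is the adjusted p with an estimated correlation. In all, preset camera called 23 of 37 lists, camera with an estimated correlation 0 and fry 2. Preset calls were lost without control replicate 3 for regulatory T cell (-0.20), macrophage (0.04), neutrophil (0.08), dendritic cell (0.04), inflammatory (0.18), epithelial-mesenchymal transition (0.07), NRF2 (0.09) and immediate early genes (0.15), and without DSF replicate 2 for neutrophil (0.41), epithelial-mesenchymal transition (0.12), mitotic (-0.03), NRF2 (0.10), pyroptosis (-0.28) and erythrocyte genes (1.14). They were also lost without DSF replicate 1 for neutrophil (0.18), inflammatory (0.50) and immediate early genes (0.14), without DSF replicate 3 for macrophage (-0.11), dendritic cell (-0.29), inflammatory (0.34) and immediate early genes (0.17), and without control replicate 1 for erythrocyte genes (1.91).

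Lists that were not called in this comparison included 2 that were written for their link to DSF, aldehyde dehydrogenases and DNA methylation genes. Aldehyde dehydrogenases had a median log2 fold change of 0.19 (preset adjusted p = 0.346) and DNA methylation genes of -0.07 (0.518). The maintenance methyltransferase Dnmt1 was at 281 ± 46.7 against 316 ± 41.8 CPM (log2 fold change -0.17 ± 0.13 SE, adjusted p = 0.674). Medians of the remaining lists were 0.11 for epithelial carcinoma markers (0.293), 0.17 for fibroblast and matrix genes (0.405), 0.37 for pericytes (0.982), 0.39 for endothelium (0.444), 0.04 for oxidative phosphorylation (0.454) and -0.05 for ribosomal proteins (0.133). For fibroblast and pericyte genes the test statistic pointed down although the medians were positive. Heat shock and metallothionein genes were at 0.08 (0.133), stress response genes of the unfolded protein pathway at -0.02 (0.493), p53 targets at 0.11 (0.325), skeletal muscle at -0.01 (0.865), adipocytes at 3.70 (0.405) and Schwann cell genes at 0.22 (0.155). Mki67, a marker of cycling cells, was at 637 ± 114 against 620 ± 82.9 CPM.

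By edgeR, 0 genes passed between DSF and control, with 1501 at an unadjusted p under 0.05 against 707 expected. The 10 genes with the smallest p, none of which passed (adjusted p = 0.187 for each), were Parp14, Ifi44, Ifi44l, Cdca7, H2-Ea-ps, Crybg1, Serpina3f and Bcl2a1d, all lower in DSF, and Gsta1 and Klf9, both higher. Gsta1, a glutathione transferase, was at 1.88 ± 0.229 against 0.284 ± 0.0971 CPM, and Klf9, which responds to glucocorticoids, at 26.2 ± 8.72 against 11.6 ± 0.445 CPM. DESeq2 called 221 genes, and edgeR called 35 without control replicate 1 and 8 without DSF replicate 1. With skin and adipocyte scores as covariates preset camera called 11 lists in place of 23. The calls ended for T cell (median 0.07), dendritic cell (0.04), regulatory T cell (0.07), B cell (-0.30), macrophage (-0.04), mast cell (-0.02), neutrophil (0.30), checkpoint (-0.17), inflammatory (0.20), epithelial-mesenchymal transition (-0.0033), hypoxia (0.10), NRF2 (-0.02), proteasome (-0.02), pyroptosis (-0.08) and skin genes (0.13).

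**Figure D2:**
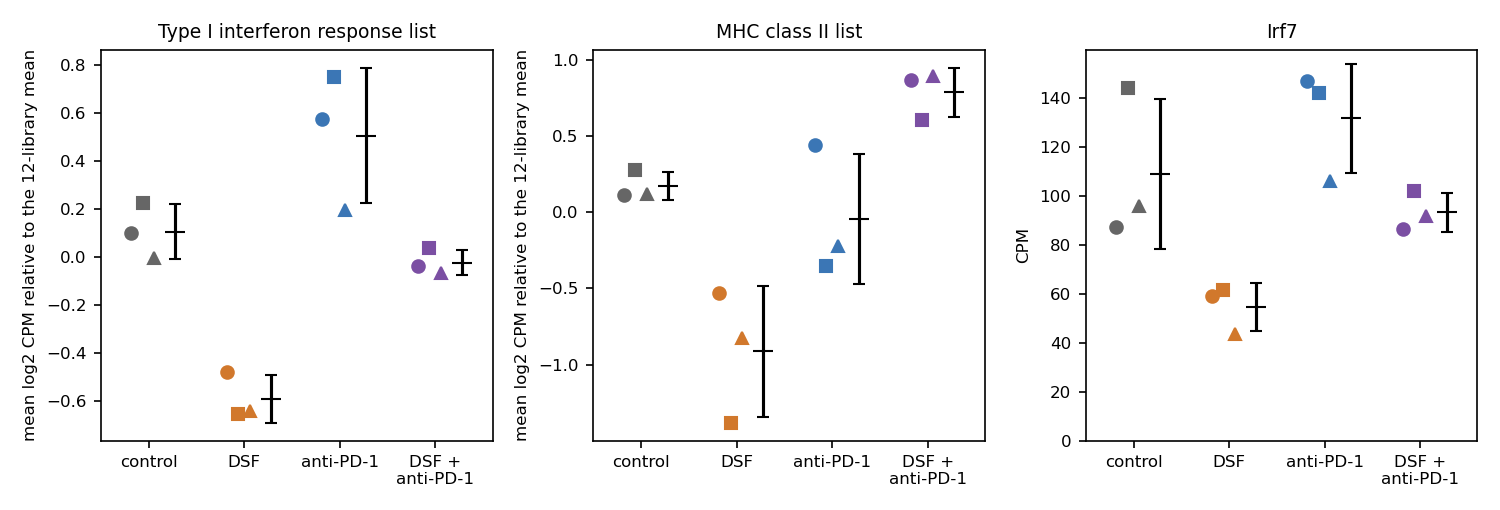
Scores of the type I interferon response list and of the MHC class II list (mean log2 CPM of the members, centred per gene) and Irf7 in CPM, for the 4 groups (circle, square and triangle are replicates 1, 2 and 3, and the black bar is the mean ± SD of 3 libraries). The DSF group was lowest in all 3 panels, with a mean interferon score of -0.59 and a mean Irf7 level of 54.6 CPM.

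Anti-PD-1 against control asks what checkpoint blockade did on its own. Type I interferon response genes had higher values in the treated tumours, with 29 of 30 log2 fold changes positive and a median of 0.40. Cmpk2, a mitochondrial nucleotide kinase induced by interferon, was at 65.2 ± 16.9 against 34.8 ± 2.67 CPM (log2 fold change 0.91 ± 0.18 SE, n = 3 each, adjusted p = 0.999), and the antiviral gene Rsad2 at 54.6 ± 13 against 28.9 ± 5.34 CPM. Of the list, 11 members rose when adjusted over the list alone and 0 over all genes. Preset camera gave an adjusted p of 4.99e-23, against adjusted p = 0.372 with an estimated correlation and 0.687 by fry. With an estimated correlation the adjusted p = 0.0159 without anti-PD-1 replicate 3, and 0.184 to 0.991 without any other single library of these groups. T cell markers had a median of -0.04 and MHC class II genes of -0.17, and neither list had a member passing when adjusted over the list alone (adjusted p = 0.919 with an estimated correlation for both). Cd8a, which marks cytotoxic T cells, was at 12.3 ± 4.73 against 13.2 ± 3.92 CPM, and Pdcd1, the gene of PD-1, at 4.05 ± 1.86 against 3.59 ± 0.848 CPM.

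The edgeR test called 0 genes between anti-PD-1 and control, as did DESeq2, with 245 genes at an unadjusted p under 0.05 where 707 are expected. The 10 smallest p-values belonged to Cmpk2, Ifih1, Ifit2 and Rsad2 of the interferon response and to Srp54c, Ppl, Ikbkg, Rbpms, Capn5 and Csnk1g2, of which Csnk1g2 alone was lower in treated tumours. Macrophage markers had a median of -0.25, negative in 20 of 20, and endothelial markers of -0.35, negative in 21 of 22 (adjusted p = 0.919 with an estimated correlation for both). Preset camera called 10 of 37 lists, or 5 without anti-PD-1 replicate 2 and 6 without replicate 3, and camera with an estimated correlation and fry called 0. Neutrophil (0.11), inflammatory cytokine (0.11) and hypoxia medians (0.14) turned to -0.13, -0.04 and -0.02 without control replicate 3, and the skeletal muscle median of -0.39 turned to 0.03 without anti-PD-1 replicate 2. The macrophage median was -0.02 without control replicate 3 and -0.09 without anti-PD-1 replicate 2, the endothelial median -0.03 without control replicate 2 and -0.17 without anti-PD-1 replicate 3, and the MHC class II median ranged from -0.45 without anti-PD-1 replicate 1 to -0.03 without anti-PD-1 replicate 3. The T cell median was -0.38 without anti-PD-1 replicate 1, where preset camera called the list lower (adjusted p = 0.499 with an estimated correlation), 0.18 without anti-PD-1 replicate 2, 0.08 without anti-PD-1 replicate 3, -0.08 and -0.0059 without control replicates 1 and 2, and -0.18 with skin and adipocyte scores as covariates, where preset camera also called it lower.

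The combination against control asks what both treatments did together. Granulocyte genes were lower in the combination tumours: Retnlg, a resistin-like protein of neutrophils, was at 1.28 ± 0.372 against 10.2 ± 8.82 CPM (log2 fold change -2.99 ± 0.63 SE, n = 3 each, adjusted p = 0.256). The neutrophil list had a median of -0.51, with 8 of 22 members falling when adjusted over the list alone and 0 over all genes (adjusted p = 0.776 with an estimated correlation). MHC class II genes had a median of 0.56, positive in 10 of 10, T cell markers of 0.47, positive in 21 of 22, dendritic cell markers of 0.59, and hypoxia and glycolysis genes of -0.29, negative in 23 of 25. For each of these lists the adjusted p = 0.776 with an estimated correlation. The interferon list had a median of -0.15 (adjusted p = 0.776 with an estimated correlation), and Irf7 was at 93.3 ± 7.86 against 109 ± 30.6 CPM. Without control replicate 1 the neutrophil median was -0.11 and the hypoxia median -0.06, and both lost the preset call, while the neutrophil median was -0.89 without control replicate 3 and the hypoxia median -0.17 without combination replicate 2. The interferon median was -0.04 without control replicate 2, which ended its preset call, and -0.26 without control replicate 3, where the dendritic cell median was 0.98.

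Skin markers were highest on average in the combination group, with a median log2 fold change of 2.22 against control and 16 of 17 members higher when adjusted over the list alone (0 over all genes, adjusted p = 0.776 with an estimated correlation). The 10 genes with the smallest p, none passing (adjusted p = 0.256 for each), included Lypd3, Lad1, Rapgefl1, Evpl, Ppl and Casz1, which are expressed in squamous epithelium, with Fam57a also higher. Ampd3, an AMP deaminase, Papln and the peroxiredoxin gene Prdx6 were lower. Lypd3 was at 31.7 ± 18.1 against 4.68 ± 1.27 CPM. No gene passed by edgeR (0 genes), with 1589 at an unadjusted p under 0.05, and DESeq2 called 250. Preset camera called 11 of 37 lists, or 7 without control replicate 1, and both camera with an estimated correlation and fry called 0. With skin and adipocyte scores as covariates the medians of T cell (-0.23, called lower by preset camera with adjusted p = 0.0162), mast cell (-0.03), hypoxia (0.09) and unfolded protein response genes (0.09) turned sign, and the preset calls ended for MHC class II (0.18), interferon (-0.05), dendritic cell (-0.06) and skin genes (0.25).

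The combination against DSF asks what anti-PD-1 added to the drug, and edgeR called genes in this pair of groups alone. It called 263 genes, 227 higher and 36 lower in the combination, with 2677 at an unadjusted p under 0.05. MHC class II genes rose together. H2-Aa (14960) was at 868 ± 81.4 CPM in the combination against 270 ± 61.4 CPM in DSF (log2 fold change 1.68 ± 0.23 SE, n = 3 each, adjusted p = 0.0387), H2-Ab1 (14961) at 766 ± 91.7 against 226 ± 52, H2-Eb1 (14969) at 509 ± 32.6 against 139 ± 42, Cd74 (16149) at 1857 ± 113 against 649 ± 155 and Ciita (12265) at 71.6 ± 1.59 against 20.9 ± 7.22. Of the 10 members, 8 rose over all genes and 10 adjusted over the list alone, with a median log2 fold change of 1.72. Libraries of the 2 groups did not overlap for the genes given, nor for 23.1% of all genes tested, where 10% would be expected by chance. The list was higher at a fry adjusted p of 0.00568, with adjusted p = 0.17 with an estimated correlation.

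Interferon and lymphocyte genes were higher in the combination than in DSF. Parp14 rose by 0.53 ± 0.10 SE on the log2 scale, Ifit2 by 0.90 ± 0.17 and Ifi44 by 0.95 ± 0.19 (adjusted p = 0.0409 for each). The type I interferon list had a median of 0.48 and 30 of 30 positive, with 3 members rising over all genes and 18 adjusted over the list alone (adjusted p = 0.223 with an estimated correlation). In the interferon gamma list (median 0.98), Ciita, the cytokine signalling inhibitor Socs1 and the immunity-related GTPase Irgm2 rose over all genes and 21 of 22 adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). T cell markers had a median of 0.99, with Bcl11b rising over all genes and 18 of 22 adjusted over the list alone (adjusted p = 0.227 with an estimated correlation). Bcl11b, which is also expressed in skin, correlated with the skin score within groups at r = 0.787, below the cut of 0.8. With skin and adipocyte scores as covariates the T cell median was -0.37, and preset camera called the list lower (adjusted p = 0.0488). The mean skin score was -1.98 in DSF and 2.17 in the combination, so that fit cannot separate skin from treatment. The NK cell receptors Klrb1c (log2 fold change 2.06) and Klrk1 (2.04) and the interleukin 2 receptor chain Il2rb (0.97) rose, within a cytotoxic list that had a median of 0.83 and 8 of 20 members rising when adjusted over the list alone (adjusted p = 0.288 with an estimated correlation). The costimulatory ligand Cd86 rose by 0.89, Cd244a by 1.39, the macrophage perforin Mpeg1 by 1.24 and the plasmacytoid dendritic cell gene Siglech by 2.59. Within groups Siglech correlated with the skin score at r = 0.621, above the skin gene Flg (0.592). The values were 0.512 for Mpeg1, 0.349 for Cd244a and 0.0108 for Cd86. Macrophage markers had a median of 0.48, with 1 member rising and 1 falling over all genes (adjusted p = 0.581 with an estimated correlation). Cd4 was at 19.6 ± 2.61 against 7.01 ± 2.87 CPM (adjusted p = 0.0572), Irf7 at 93.3 ± 7.86 against 54.6 ± 9.84 CPM (adjusted p = 0.0695) and Cd274 at 94.9 ± 5.74 against 66.2 ± 18.9 CPM (adjusted p = 0.249), none of which passed.

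Granulocyte, metallothionein and hypoxia genes were among the lower genes named, as the naming rule draws on lists called by preset camera. Of the 36 lower genes, 4 were in the neutrophil list, 2 in the heat shock and metallothionein list and 2 in the hypoxia list. S100a8 (20201) and S100a9 (20202), which form calprotectin in neutrophils and other myeloid cells, fell by 1.84 ± 0.39 SE and by 1.90 ± 0.43 SE on the log2 scale (adjusted p = 0.0433 and 0.0499). Retnlg was at 1.28 ± 0.372 CPM in the combination and 17.2 ± 4.56 CPM in DSF (log2 fold change -3.75), the platelet chemokine Ppbp had a log2 fold change of -3.76, and the neutrophil gelatinase Mmp9 of -1.82. The neutrophil list had a median of -0.86, with 4 of 22 members falling over all genes and 10 adjusted over the list alone (adjusted p = 0.308 with an estimated correlation). The metal-binding metallothioneins Mt1 (200 ± 43.3 against 554 ± 104 CPM) and Mt2 (258 ± 69.5 against 649 ± 79.4 CPM) fell with log2 fold changes of -1.47 and -1.33, while the other members of the heat shock and metallothionein list did not pass. Bnip3, a mitophagy receptor induced by hypoxia, fell by 0.97 and the collagen prolyl hydroxylase P4ha1 by 0.85. All 25 hypoxia and glycolysis genes were negative (median -0.45), and 15 of them fell when adjusted over the list alone (adjusted p = 0.228 with an estimated correlation). With skin and adipocyte scores as covariates the hypoxia median was -0.04 and its preset call ended. Papln also fell, with a log2 fold change of -1.51. Looked up after the values were seen, the smallest p among all genes was that of Ampd3, at 45.2 ± 1.26 against 93.3 ± 9.56 CPM (log2 fold change -1.05 ± 0.11 SE, adjusted p = 0.0223).

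Among the largest rises were those of skin genes, in step with the skin marker shares above. Foxn1 (log2 fold change 6.06 ± 1.3 SE), a transcription factor of hair follicles, Bpifc (5.88), Gsdma (5.33), Lce6a (5.25), filaggrin Flg (5.15 ± 0.77 SE), Cpa4 (5.08) and Crct1 (5.07) rose, and Flg was at 62.2 ± 36.1 against 1.73 ± 1.41 CPM. The skin list had a median of 3.96, with 10 of 17 members rising over all genes and 17 adjusted over the list alone (adjusted p = 0.2 with an estimated correlation). Of the 227 higher genes, 84 (37%) followed the skin score within groups with r above 0.8, compared with 3.38% of all genes tested and 0 of the 36 lower genes. The median r was 0.739 for the higher genes, -0.342 for the lower genes and -0.0106 for all genes tested. Skin genes such as Flg (0.592) and Foxn1 (0.71) lay under the cut, so the higher genes not counted are not thereby free of skin. The cut counts positive correlations only, and the lower genes reached -0.869 (Ampd3). Gsdma, a gasdermin of the epidermis, was also the member of the pyroptosis list that rose. Mast cell markers, with a median of 1.45, had 8 of 11 members rising when adjusted over the list alone and 0 over all genes (adjusted p = 0.26 with an estimated correlation), and the median was 0.12 with the covariates, which ended the preset call.

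These calls depended on single libraries. Without DSF replicate 2, the library with the adipocyte markers, 601 genes were called, of which 211 were among the 263, and all 263 kept their sign. Without combination replicate 1, 334 genes were called, of which 210 were among the 263. The number was 28 without DSF replicate 1 and 0 without DSF replicate 3, combination replicate 2 or combination replicate 3. With skin and adipocyte scores as covariates 0 genes passed, the MHC class II median was 0.92, and the fold changes of Foxn1, Gsdma, Cpa4, Bcl11b, Dmkn and P4ha1 and the medians of regulatory T cell (-0.42), macrophage (-0.30, called lower by preset camera with adjusted p = 0.014), NRF2 (0.04) and proteasome genes (-0.01) turned sign. In the same fit the medians were 0.16 for dendritic cells, 0.44 for cytotoxic cells, 0.76 for type I interferon genes and -1.36 for neutrophils. DESeq2 called 1170 genes, limma on FPKM 431, edgeR on the 6 libraries of both groups alone 0, the stricter filter 130 and limma-voom with library weights 8. Among the lists, preset camera called 21 of 37, fry 13 and camera with an estimated correlation 0.

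**Figure D3:**
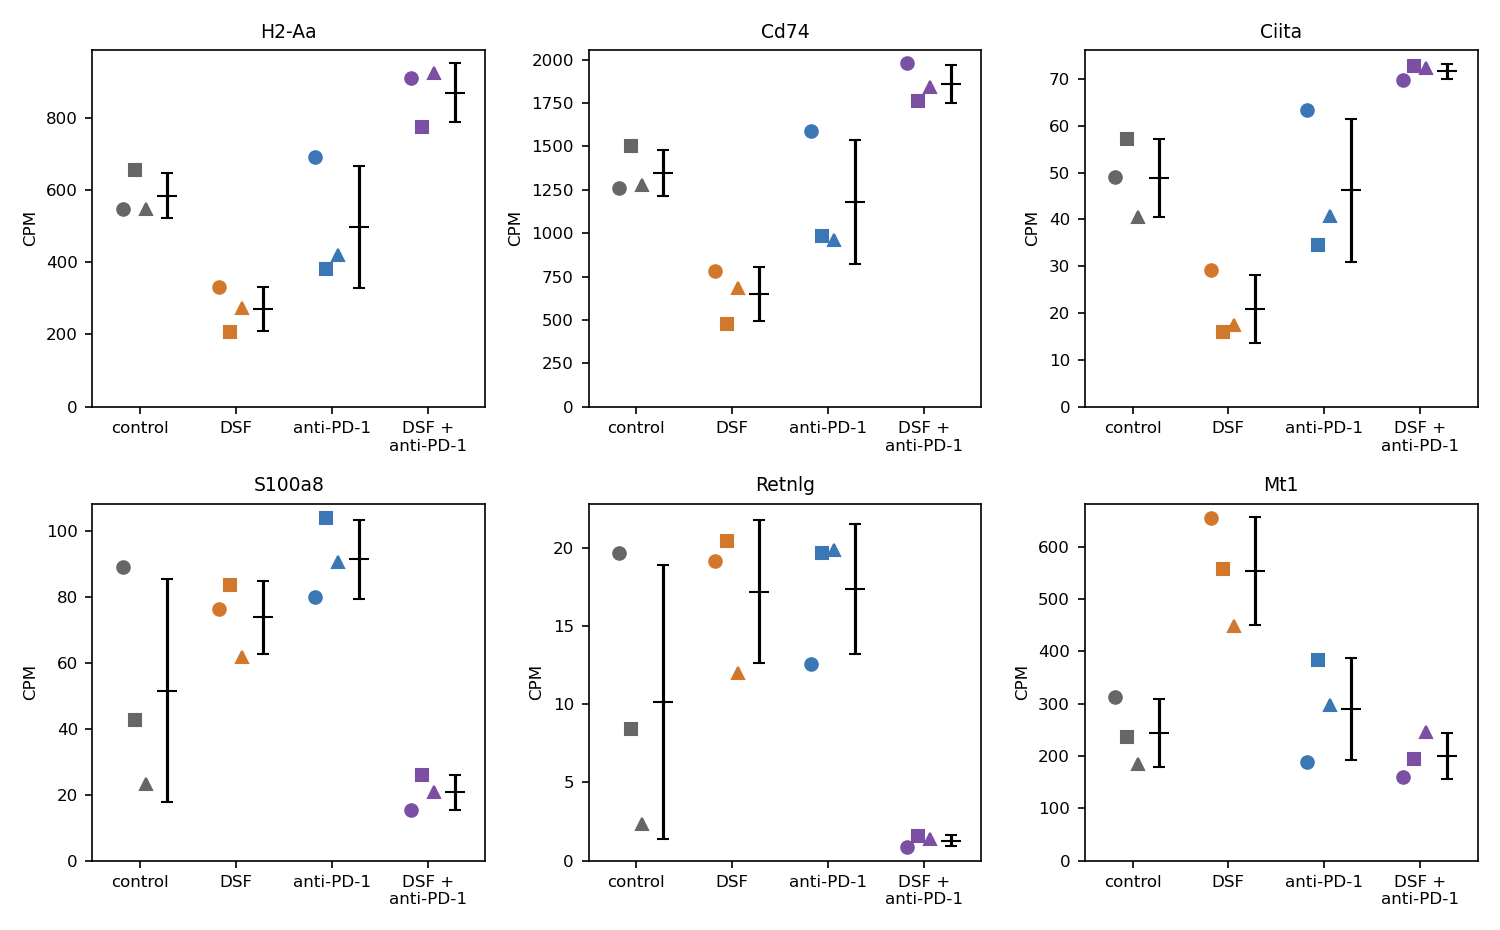
CPM of H2-Aa, Cd74, Ciita, S100a8, Retnlg and Mt1 in the 12 libraries by group (circle, square and triangle are replicates 1, 2 and 3, and the black bar is the mean ± SD of 3 libraries). For each gene the combination and DSF libraries did not overlap, with H2-Aa at 868 CPM against 270 CPM and S100a8 at 20.7 CPM against 73.9 CPM on average.

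The combination against anti-PD-1 asks what the drug added to checkpoint blockade. Interferon-stimulated genes had lower values with DSF here too, with 30 of 30 negative and a median of -0.57. Cmpk2 was at 32.5 ± 3.43 against 65.2 ± 16.9 CPM (log2 fold change -1.0 ± 0.18 SE, n = 3 each, adjusted p = 0.413) and Rsad2 at 24.2 ± 4.82 against 54.6 ± 13 CPM. In the list 20 members fell when adjusted over the list alone and 0 over all genes, with adjusted p = 0.525 with an estimated correlation. Without anti-PD-1 replicate 3 the adjusted p = 0.0257 with an estimated correlation, and without any other single library of these groups it was 0.278 to 0.574. S100a8 was at 20.7 ± 5.34 against 91.7 ± 12.2 CPM, Retnlg at 1.28 ± 0.372 against 17.4 ± 4.15 CPM, and the neutrophil list had a median of -0.64, with 7 of 22 members falling when adjusted over the list alone and 0 over all genes (adjusted p = 0.535 with an estimated correlation). MHC class II genes had a median of 0.73, with 8 of 10 members rising when adjusted over the list alone and 0 over all genes (adjusted p = 0.535 with an estimated correlation). Skin markers, again highest on average in the combination group, had a median of 1.87, with 12 of 17 members rising when adjusted over the list alone and 0 over all genes (adjusted p = 0.535 with an estimated correlation).

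Between the combination and anti-PD-1 edgeR called 0 genes, with 1452 at an unadjusted p under 0.05, 70 called by DESeq2 and 4 by edgeR on both groups alone. The 10 smallest p-values (adjusted p = 0.413 for each) belonged to Retnlg, Prok2, Cmpk2, S100a8 and Rsad2, which were lower in the combination, and to Serinc2, Ifitm10, Nectin1, Lypd3 and Ephb6, which were higher. Preset camera called 18 of 37 lists, and camera with an estimated correlation and fry called 0. With skin and adipocyte scores as covariates preset camera called 8 lists, and the medians of T cell (-0.15), macrophage (-0.04), unfolded protein response (0.04) and skin genes (-0.15) turned sign.

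The interaction tests whether the change with DSF differed in the presence and absence of anti-PD-1. MHC class II genes stood out: their median log2 change with DSF was -1.17 without anti-PD-1 and 0.73 with it, and the interaction had a median of 1.90 with 10 of 10 positive. Of these genes 9 rose when adjusted over the list alone and 0 over all genes (fry adjusted p = 0.0254, adjusted p = 0.256 with an estimated correlation). The interferon gamma list had a median of 1.07, with 18 of 22 members rising when adjusted over the list alone and 0 over all genes, and the T cell list of 1.08, with 0 members rising by either count (adjusted p = 0.256 with an estimated correlation for both). Hypoxia and glycolysis genes had a median of -0.52, negative in 25 of 25, with 11 falling when adjusted over the list alone and 0 over all genes, and skin markers of 3.38, with 15 of 17 rising when adjusted over the list alone and 0 over all genes (adjusted p = 0.256 with an estimated correlation for both). Type I interferon genes had an interaction median of 0.17 (adjusted p = 0.647 with an estimated correlation), against -0.68 and -0.57 for the change with DSF in the absence and presence of anti-PD-1.

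The interaction test of edgeR called 0 genes, with 1754 at an unadjusted p under 0.05 and 235 called by DESeq2, while 19 passed without anti-PD-1 replicate 1 and 4 without DSF replicate 1. Preset camera called 25 of 37 lists, fry 1 and camera with an estimated correlation 0. With skin and adipocyte scores as covariates the medians of T cell (-0.14), regulatory T cell (-0.38), B cell (-0.48), macrophage (-0.07), epithelial-mesenchymal transition (0.01) and skin genes (-0.23) turned sign, while those of hypoxia and MHC class II genes were -0.19, which ended the preset call, and 1.18. The interferon median was 0.34 with the covariates, and 0.11, 0.01, 0.08 and 0.02 without control replicate 1, control replicate 2, DSF replicate 2 and anti-PD-1 replicate 3.

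The main effects compare 6 libraries with 6. Interferon-stimulated genes were lower in tumours given DSF, with or without anti-PD-1: all 30 were negative with a median of -0.63, and 28 fell when adjusted over the list alone and 0 over all genes. Irf7 was at 74 ± 22.6 CPM with DSF and 120 ± 26.9 CPM without (SD, n = 6 each; log2 fold change -0.75 ± 0.14 SE, adjusted p = 0.221). The list fell at an adjusted p = 0.0465 with an estimated correlation and 0.00479 by fry. Without anti-PD-1 replicate 2 or 3 the adjusted p was 0.0322 or 0.004 with an estimated correlation, and without any single one of the other 10 libraries it was 0.0681 to 0.172. The interferon score differed by -0.61 ± 0.09 SE, with an exact permutation p of 0.005, the smallest these 400 arrangements can give, and 0.185 after adjustment over 37 lists. By edgeR 0 genes passed, with 1153 at an unadjusted p under 0.05, 80 called by DESeq2 and 3 by edgeR without anti-PD-1 replicate 3. The 10 smallest p-values belonged to Parp14, Cmpk2 and Ifi44 (adjusted p = 0.0843 for each), Ifih1, Ifit1, Ifit2, Ifit3, Usp18 and Eif2ak2, all interferon-induced and lower with DSF, and to Serinc2, which was higher (49.3 ± 3.98 against 36.4 ± 2.36 CPM, adjusted p = 0.14). Preset camera called 12 lists, or 7 without control replicate 1, and the interferon list was the single call of fry and of camera with an estimated correlation.

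In the main effect of anti-PD-1 the same interferon list was higher, with 30 of 30 positive, a median of 0.45, and 25 members rising when adjusted over the list alone and 0 over all genes. It had a fry adjusted p of 0.024 and an exact permutation p of 0.01 for the score (0.333 after adjustment over 37 lists). With an estimated correlation the adjusted p = 0.149, or 0.0262 without anti-PD-1 replicate 3, and the list did not pass by that test without any other single library. MHC class II genes had a median of 0.77, with 9 of 10 rising when adjusted over the list alone and 0 over all genes (fry adjusted p = 0.0325, adjusted p = 0.149 with an estimated correlation), and skin markers of 2.19, with 16 of 17 rising when adjusted over the list alone and 0 over all genes (fry adjusted p = 0.0325, adjusted p = 0.149 with an estimated correlation). Ampd3 was at 55.5 ± 12.9 CPM with anti-PD-1 and 80.1 ± 15.8 CPM without (log2 fold change -0.53 ± 0.08 SE, adjusted p = 0.16). The other 9 smallest p-values, each with the same adjusted p of 0.16, were those of the interferon genes Ifit2, Ifit3, Cmpk2 and Ifih1, the skin genes Flg, Lce1c and Lce1a2, Nkpd1, and Papln, which was lower. By edgeR 0 genes passed, with 1422 at an unadjusted p under 0.05, 321 called by DESeq2, and 16 and 1 by edgeR without anti-PD-1 replicates 2 and 3. Preset camera called 19 lists, fry 5 and camera with an estimated correlation 0, and the covariates brought the medians of MHC class II and skin genes to 0.33 and 0.09 and turned those of T cell (-0.25, called lower by preset camera with adjusted p = 0.00555), regulatory T cell (-0.18), mast cell (-0.10), hypoxia (0.07), NRF2 (0.07) and proteasome genes (-0.03).

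Changes against control were compared between arms. By edgeR 0 genes were shared by any pair of arms, since 0 genes passed, and by DESeq2 the DSF and combination arms shared 3 higher and 8 lower genes. How many DESeq2 would share without any change, given the common controls, was not simulated. The fold changes correlated across genes at 0.187 between the DSF and anti-PD-1 arms, -0.01 between DSF and combination and 0.376 between anti-PD-1 and combination. Arms without any change gave 0.501, 0.499 and 0.499 in simulation, because the 3 control libraries are shared. The covariances of 0.0312, -0.00326 and 0.0714 all lay below the simulated 0.0863, 0.0863 and 0.0859. Simulated libraries, controls included, had dispersions estimated over all groups, which need not be the spread of the real controls. Values below the simulated ones therefore do not show that the arms shared less than unchanged arms would.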

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

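All 3 tests of explanations in this part were chosen after the result was seen. The MHC class II list is given here because it was the 1 list whose interaction of DSF and anti-PD-1 passed by fry. The fry value below is thus the rule of choice and adds no further evidence. The interaction had a median log2 value of 1.9, positive in 10 of 10 genes, with H2-Aa at 1.91 ± 0.32 SE, Cd74 at 1.71 and Ciita at 1.86. No gene of the list passed over all genes in the interaction (adjusted p = 0.232 for H2-Aa), and the adjusted p of the list was 0.256 with an estimated correlation and 0.0254 by fry.

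The pattern weighed is the lower MHC class II level in the DSF libraries than in the combination libraries. Adipose tissue in DSF replicate 2 is argued against as its whole cause, because the median log2 fold change was 1.51 without that library, against 1.72 with it. Skin in the combination libraries as the whole cause was weighed by DSF against control, which leaves those libraries out and had a median of -1.17. Skin markers were lower in DSF there too (median -1.51, 0.0138% and 0.0329% of the counts). That comparison therefore cannot separate skin from the MHC class II change. The combination lay above control for MHC class II (median 0.56) and for skin markers (2.22). With the skin and adipocyte covariates the MHC class II medians were -0.74 in DSF against control and 0.92 in the combination against DSF. In the combination against control the median was 0.18 with the covariates, and the preset call ended. The skin score differs between these groups, so the covariate fit cannot tell skin from treatment and decides nothing here. A lower share of all immune cells alike is argued against by the difference of 1.31 between the changes in the MHC class II and macrophage scores, with a pooled SD of 0.62 and n = 3 per group, and by the neutrophil score, which was 0.36 in DSF and -0.744 in the combination. The T cell (-0.532 and 0.539), dendritic cell (-0.4 and 0.599) and cytotoxic scores (-0.469 and 0.45) were higher in the combination together with MHC class II, so a lower share of these cells in DSF tumours stays open, as does an effect of the treatments on these genes, and neither was tested.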

How the results depend on the processing

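The voom fit with library weights, the skin and adipocyte covariates, the fits that leave DSF replicate 2 out of the spread and the removal of genes following the skin score were chosen after the data were seen. The pseudocount alternatives were not run, since the table holds counts, and fry was not recomputed with libraries left out. For the combination against DSF, 263 genes by edgeR became 1170 by DESeq2, 130 with at least 5 CPM in 3 libraries, 0 with the 2 groups alone, 7 with replicate number as a block, 431 by limma on FPKM, 8 by voom with weights, 0 with the covariates and 19 without the genes following the skin score, which removes called genes by construction. DESeq2 called 870 genes for any difference, 221 for DSF against control, 250 for the combination against control, 70 for the combination against anti-PD-1, 235 for the interaction, 80 for the DSF main effect and 321 for the anti-PD-1 main effect, each against 0 by edgeR, and 11 genes shared between arms against 0. The combination against anti-PD-1 had 4 genes with the 2 groups alone. The libraries share only a replicate number: among 18 pairs with the same number in different groups the deviations from the group means correlated at -0.365 to 0.462, over 0.1 in 10 and under -0.1 in 4, and 10 of the 18 correlated best with their own number (all 3 pairs of control with the combination did both, and all 3 of control with DSF the latter), while the replicate block gave 0 genes in each of the other 8 tests. With size factors of the RLE method or no filter on low counts, all 9 counts of genes stayed within 1.5 times. The cause of these differences was not tested. With single libraries left out, the numbers of genes ranged from 0 to 41 for any difference, 0 to 35 for DSF against control, 0 to 601 for the combination against DSF, 0 to 19 for the interaction, 0 to 3 for the DSF main effect and 0 to 16 for the anti-PD-1 main effect, and were 0 throughout for the other 3 comparisons.

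The numbers of lists called by preset camera, camera with an estimated correlation and fry were 23, 0 and 2 for DSF against control, 10, 0 and 0 for anti-PD-1 against control, 11, 0 and 0 for the combination against control, 21, 0 and 13 for the combination against DSF, 18, 0 and 0 for the combination against anti-PD-1, 25, 0 and 1 for the interaction, 12, 1 and 1 for the DSF main effect and 19, 0 and 5 for the anti-PD-1 main effect. With the covariates preset camera called 11 lists for DSF against control, 7 for the combination against control, 8 for the combination against anti-PD-1 and 10 for the interaction. With single libraries left out it called 17 to 27, 5 to 15, 7 to 16, 17 to 25, 13 to 21, 20 to 25, 7 to 16 and 16 to 22 lists in the order above.

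The covariates reversed 6 reported genes of the combination against DSF: Foxn1 (-3.765), Gsdma (-1.414), Cpa4 (-0.080), Bcl11b (-0.55), Dmkn (-0.28) and P4ha1 (0.10). They also reversed lists in both median and test direction. These were T cell 0.068, dendritic cell 0.04 and NRF2 -0.017 for DSF against control, and T cell -0.23, mast cell -0.031, hypoxia 0.094 and unfolded protein response 0.086 for the combination against control. For the combination against DSF they were T cell -0.37, regulatory T cell -0.42, macrophage -0.30, NRF2 0.044 and proteasome -0.006267, and against anti-PD-1 T cell -0.15, macrophage -0.042, unfolded protein response 0.040 and skin -0.15. In the interaction they were T cell -0.14, regulatory T cell -0.38, B cell -0.48, macrophage -0.071, epithelial-mesenchymal transition 0.0053 and skin -0.23, and in the anti-PD-1 main effect T cell -0.25, regulatory T cell -0.18, mast cell -0.10, hypoxia 0.069, NRF2 0.074 and proteasome -0.028. Skin genes lose their change by construction, and the cause of the other reversals was not tested. With single libraries left out, the medians of anti-PD-1 against control ranged from -0.13 to 0.57 for neutrophil, -0.041 to 0.31 for inflammatory and -0.025 to 0.24 for hypoxia genes (lowest without control replicate 3, highest without control replicate 1) and from -0.82 to 0.028 for skeletal muscle (highest without anti-PD-1 replicate 2). The fibroblast median of the combination against DSF ranged from -0.25 without DSF replicate 1 to 1.11 without DSF replicate 2, and without DSF replicate 2 the endothelial medians reached -0.049 in the DSF main effect (up to 0.63) and 0.028 in the anti-PD-1 main effect (down to -0.57). Among values for single genes, the RLE method left 595 on the same side of the threshold and direction and moved 2. DESeq2 left 441, moved 2 and brought 154 past the threshold. Values counted as moved are those not called whose sign turned. Among values for single genes and lists together, the covariates left 527, moved 87, weakened 88 and reversed 34 called ones, so the moved values turned sign as well.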

Other observations

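Of the tests in this part, those of combination replicate 2 were chosen after its skin genes were seen, and the genes of this paragraph were chosen after their values were seen. Mt1, Mt2, Ampd3 and Gsta1 had their highest mean levels with DSF alone. The whole heat shock and metallothionein list took 1.12% of the counts in control and 1.07% in DSF, with mean scores of -0.0881 and 0.159. Mt1 was at 554 ± 104 CPM in DSF, against 245 ± 64.9 in control, 290 ± 97.8 in anti-PD-1 and 200 ± 43.3 CPM in the combination (SD, n = 3 each), and Mt2 at 649 ± 79.4, 309 ± 56.9, 349 ± 101 and 258 ± 69.5 CPM in the same order. The AMP deaminase gene Ampd3 was at 93.3 ± 9.56 CPM in DSF, 66.8 ± 2.86 in control, 65.8 ± 9.84 in anti-PD-1 and 45.2 ± 1.26 CPM in the combination, and the glutathione transferase gene Gsta1 at 1.88 ± 0.229, 0.284 ± 0.0971, 0.682 ± 0.288 and 0.667 ± 0.145 CPM. The interaction log2 values were -1.71 for Mt1 (adjusted p = 0.259), -1.51 for Mt2 (0.259), -1.02 for Ampd3 (0.232) and -2.72 for Gsta1 (0.259), and none passed.

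Skin genes were high in combination replicate 2. Of 42 hair and melanocyte genes listed, 11 were tested. Skin carried into that tumour piece may be the source, because 10 of these 11 had their highest level there, with S100a3 at 178 CPM, Krt75 at 194, Dct at 82.4 and Pmel at 43.5 CPM. The margin was small for Mitf (21.7 CPM, against 20.9 in control replicate 2), and Mlph was highest in DSF replicate 2 (4.93 against 4.23 CPM). The median ratio of the 11 genes to the other libraries, 25.2, argues against squamous differentiation of the tumour cells alone, which would not bring melanocyte genes. In combination replicates 1 and 3 the hair and melanocyte genes had a median log2 fold change of 1.62 against DSF, and there skin in the tumour pieces and other sources cannot be told apart, since their median level was 2.61 CPM and 9 of 11 were higher than in DSF. A treatment effect on skin over the tumour was not tested.

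Type I interferon genes were lower in the libraries given DSF. Adipose tissue in DSF replicate 2 is argued against, since the median of the DSF main effect was -0.572 without that library. A lower share of immune cells alike is argued against, since the interferon score fell further than the mean of 5 immune cell scores by -0.502 ± 0.176 SE (n = 6 per group). That mean changed by -0.11 ± 0.15 SE, but it hides opposite moves. In DSF, control, the combination and anti-PD-1 the T cell score was -0.532, 0.0427, 0.539 and -0.0496. The neutrophil score was 0.36, 0.0769, -0.744 and 0.307, and the interferon score -0.59, 0.106, -0.0223 and 0.506, in the same order. A lower share of T cells with DSF alone therefore stays open. An effect of DSF on the type I interferon genes stays open too and was not tested apart from the comparison itself. The list passed with an estimated correlation (adjusted p = 0.0465), but without any single one of 10 of the 12 libraries that adjusted p was 0.0681 to 0.172.

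Other splits of the libraries into groups of the same sizes were fitted for each count. Where the real number of genes is 0, every split has at least as many, so the count of splits tests nothing. This holds for 10 of 10 splits for DSF against control (highest other 15), anti-PD-1 against control (0), the combination against control (0) and the combination against anti-PD-1 (0), and for 100 of 100 regroupings of the 12 libraries for any difference (0), the interaction (751), the DSF main effect (2) and the anti-PD-1 main effect (1). For the combination against DSF, 1 of 10 splits, the real one, called as many genes (263, highest other 0), and 10 splits are too few for a share under 0.05. The regroupings with the most genes in the interaction called 751, 625 and 581, and why they called so many was not examined.

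For lists by preset camera the splits of pairs are too few for a share under 0.05 as well. As many were called in 2 for DSF against control (real value 23, highest other 24), 8 for anti-PD-1 against control (10 and 23), 7 for the combination against control (11 and 20), 1 for the combination against DSF (21 and 19) and 2 for the combination against anti-PD-1 (18 and 20). Among 100 regroupings, the real one included, as many lists were called in 3 for the interaction (25 and 25), a share under 0.05. The number was 77 for the DSF main effect (12 and 25) and 30 for the anti-PD-1 main effect (19 and 25), where chance is not excluded. The share for the interaction was not corrected for the number of counts compared, and camera with an estimated correlation called 0 lists there. Chance is therefore not excluded for the interaction either.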
